A study of Homo sapiens with 6 samples.

How the data were processed

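Total RNA of both lines, extracted with Trizol, was labelled as biotinylated cRNA and hybridised to U133 Plus 2.0 arrays, with 3 arrays per line, per the labels' protocols. The deposited values are MAS5 signal intensities, 1 per probe set and array, per the submitters' processing notes. Background settings and the version of MAS5 are not given in the sources used here. The values were linear, above 0 and at most 41829, and their mean trimmed by 2% at both ends was about 500.07 on each array, so the authors' scaling was kept. Detection calls were not used here, so a low signal could not be told from background array by array. Signals near the top of the range can be compressed. The number of arrays limits the precision.

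Probe sets were named from the platform annotation, with symbols updated through gene identifiers against the RefSeq gene table of assembly GRCh38.p14, which was used for symbols and gene order only. Of 54675 probe sets, 62 array controls were left out, 41091 had 1 gene symbol, 1801 had several and 11721 had none, and 41043 matched the RefSeq table. Genes whose probe sets carry no single symbol, CASP3 among them, were not analysed here. Each gene was represented by its brightest probe set, by mean log2 value over the 6 arrays, which gave 19775 genes. Among 10523 genes with several probe sets, 6161 had at least 1 called and 187 (3.04%) had probe sets called in both directions.

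Signals were used as log2(signal + 17), where 17 is the 25th percentile of all values, so differences of dim genes are understated. The lines were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 (R 4.3.3), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are MCF-7/ADR minus MCF-7 on the log2 scale, with the moderated standard error (SE). Signals are mean ± SD of the linear values. Rose, fell, higher and lower refer to this test. Adjusted p-values of single genes were 0.029 or less for all genes called in the text, and are printed for the genes that were always to be named.

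The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took ABCB1, ESR1, TOP2A, CASP3 and PAX8 always; the 10 genes with the largest difference in each direction among called genes without overlap between the lines and above the median level in the brighter line; and, in each list, up to 3 called members with the largest difference and the largest in the opposite direction. VIM, ZEB1, EPCAM, GAPDH, GATA3, FOXA1, PGR, CDKN1A, MDM2, NQO1 and CD44 were chosen after their values were seen. TOP2B was also chosen after its values were seen, and was not followed through the alternatives.

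There were 29 lists, none chosen on these samples: ABC transporters, ABCB1 neighbours, anthracycline targets, glutathione defence, oestrogen response, luminal, epithelial, mesenchymal, basal, Mullerian, haematopoietic, endothelial and fibroblast markers, genes deleted and amplified in MCF-7, cell cycle, p53 targets, apoptosis, interferon, antigen presentation, cytokines, TGF-beta, integrins and matrix, stem cell genes, glycolysis, cholesterol synthesis, break repair, cancer-testis antigens and ribosomal proteins. They were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists. Camera compares a list with all other genes. The call of 13 lists (6 higher, 7 lower) became 3 with a correlation estimated per list: oestrogen response, the amplified genes and cholesterol synthesis. The fry test, which does not compare a list with other genes, was an alternative. Control ratios were tested with exact permutation tests.

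On simulated arrays with the same 19775 genes, the test recovered 18% of 50 genes changed by 0.5 on the log2 scale, 52% at 1, 96% at 2 and 98% at 3, all of them genes above the median level. It made 6 false calls among 138. The real comparison called 8529 genes, where the adjustment is less strict, so these shares do not give its power. A shifted list was recovered and 0 unshifted lists were called. Simulated genes varied independently of each other, so false calls of lists with correlated genes were not tested. Alternatives covered the offset, a floor, scaling by quantiles, medians or 75th percentiles, a filter on dim genes, the choice of probe set, the variance model, the replicate number as a block and leaving out each array.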

Results

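RNA levels were measured in a pair of human cell lines on Affymetrix U133 Plus 2.0 arrays, which read the 3' ends of transcripts with short DNA probes. MCF-7 is an oestrogen receptor positive breast cancer line of luminal, gland-lining type. MCF-7/ADR is a line of that name kept in doxorubicin (adriamycin), an anthracycline drug that poisons topoisomerase II. It was grown with 1 µg/ml doxorubicin and kept free of the drug for 1 week before use. The origin of its stock is not stated in the sources used here. Each line was measured on 3 arrays, labelled as biological replicates. The 2% trimmed mean signal was between 500.067 and 500.079 on all 6 arrays, and the brightest probe set reached 41829. MCF-7/ADR replicate 1 stood apart in its dim probe sets, with a median signal of 103.7 against 58.3 to 64.3 on the other arrays. Its 25th percentile was 29.2, against 14.5 to 15.8 on the others. Log2 values correlated across genes with r between 0.958 and 0.978 for the 6 pairs of arrays within a line and between 0.862 and 0.880 for the 9 pairs between lines. Genes are not independent replicates, so these are descriptions of the arrays.

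The comparison asked which genes differed between MCF-7/ADR and MCF-7. ABCB1, which encodes the drug efflux pump P-glycoprotein, had a signal of 18324 ± 1228 (SD, n = 3) in MCF-7/ADR and 26.2 ± 4.64 in MCF-7. ESR1, the oestrogen receptor alpha gene, went the other way, with 23.3 ± 7.93 in MCF-7/ADR and 7996 ± 224 in MCF-7. Of its 9 probe sets, 2 were lower and none was higher. TOP2A, a topoisomerase II gene, did not pass the test, with 3098 ± 128 in MCF-7/ADR and 3063 ± 885 in MCF-7. TOP2B, the other topoisomerase II gene, was lower in MCF-7/ADR, at 3902 ± 188 against 7054 ± 859, a log2 difference of -0.85 (SE 0.10). PAX8, a transcription factor of kidney, thyroid and Mullerian tissues, was higher in MCF-7/ADR, at 1923 ± 132.98 against 413 ± 42.8. The log2 differences, MCF-7/ADR minus MCF-7, were 8.73 (SE 0.12, limma adjusted p = 8.5e-11) for ABCB1, -7.65 (SE 0.16, adjusted p = 9.7e-10) for ESR1, 0.06 (SE 0.18, adjusted p = 0.84) for TOP2A and 2.18 (SE 0.11, adjusted p = 2.6e-07) for PAX8. CASP3 was not analysed here. For each gene reported here as higher or lower, the 3 arrays of one line lay above the 3 of the other.

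Beyond these genes, the highest values in MCF-7/ADR relative to MCF-7 belonged to LY6K, a surface antigen, with a log2 difference of 9.40 (SE 0.22), and MMP1, an interstitial collagenase, with 9.30 (SE 0.09). GPX1, a glutathione peroxidase, followed with 9.06 (SE 0.22). The neurofilament gene NEFH (8.56), the actin-binding genes CNN3 (8.51) and CALD1 (8.48), the transcription factor ETS1 (8.41), TCEAL9 (8.19) and the serine synthesis gene PSAT1 (8.18) completed the 10 largest together with ABCB1. On the other side, the luminal keratin KRT19 had a signal of 2.71 ± 1.30 in MCF-7/ADR and 31418 ± 1260 in MCF-7, a log2 difference of -10.64 (SE 0.11). The epithelial cadherin CDH1 (-10.04), the ubiquitin gene UBB (-9.95), the secretory gene AGR2 (-9.60) and the long non-coding RNA DSCAM-AS1 (-9.0) came next. SULF2 (-9.0), TFF1 (-8.82), MAL2 (-8.66), LXN (-8.45) and DNAJC15 (-8.44) completed that group. In the dimmer line each of these genes had a mean signal of 50.7 or less, so sizes and order depend on the offset added before logs. With 4 times the offset MMP1 came first at 8.21, ahead of LY6K, and 9 of the 10 in each direction stayed. Of 19775 genes tested, 8529 (43.1%) differed, 4305 higher and 4224 lower in MCF-7/ADR, and by at least 2-fold 2547 were higher and 2280 lower. More were lower than higher under each other scaling, with 2653 higher and 4141 lower (2111 and 3064 by 2-fold) with arrays centred on their medians, 4241 and 4480 (2364 and 2482) with quantile normalisation and 3891 and 4355 (2415 and 2476) with 75th percentile scaling. The same held above the median level, with 3302 and 3712 (1443 and 1669). The arrays of the lines did not overlap for 10075 genes (50.9%), where chance gives 10%. Without MCF-7/ADR replicate 1, 8333 genes were called, 4037 higher and 4296 lower (2401 and 2460 by 2-fold), of which 7862 were among the 8529.

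**Figure D1:**
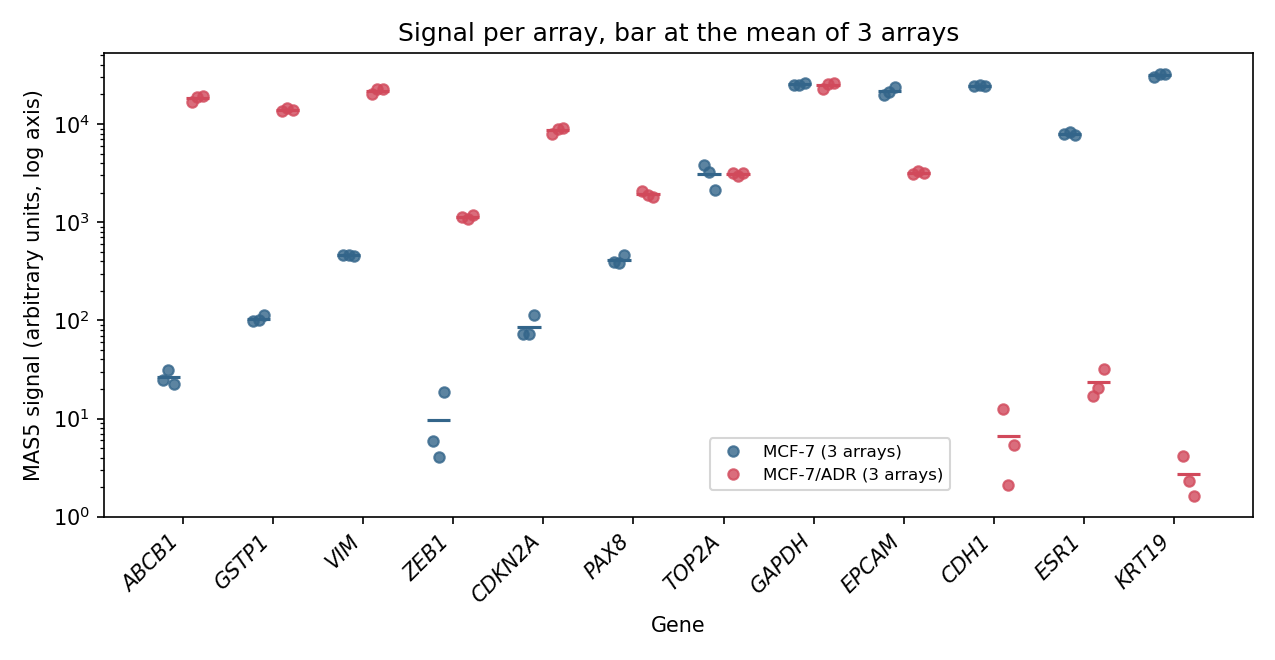
MAS5 signal (arbitrary units, log axis) of 12 genes on each of the 3 MCF-7 arrays (blue) and the 3 MCF-7/ADR arrays (red), with a bar at the mean of the 3. ABCB1 lay near 26.2 in MCF-7 and 18324 in MCF-7/ADR, KRT19 near 31418 and 2.71, and TOP2A overlapped between the lines.

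Genes of drug transport and drug chemistry moved in both directions. Among 15 ABC transporters and the vault protein gene measured as a list, 5 rose and 3 fell (5 and 3 adjusted over the list alone). ABCB4, whose sequence is close to that of ABCB1, had a log2 difference of 3.29 (SE 0.32). Cross-hybridisation between this pair was not resolved. ABCC3, an exporter of organic anions, fell by 4.96 (SE 0.26), a call lost when probe sets shared between transcripts were left out (-0.25). The list was not shifted against other genes (camera adjusted p = 0.52). Of 13 neighbours of ABCB1 in band 7q21, 7 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.052). ABCB4 was among the 7 that rose and had the largest difference of the list. The count and the test thus include a signal that cross-hybridisation may have raised. TP53TG1 (-1.77) and ELAPOR2 (-1.68) were the neighbours that fell.

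Of 14 genes of anthracycline targets and carbonyl reduction, 3 rose and 9 fell (3 and 9 adjusted over the list alone). The aldo-keto reductase AKR1C1, which reduces carbonyl groups of steroids and drugs, fell from 8357 ± 486 in MCF-7 to 451 ± 32.0 in MCF-7/ADR, a log2 difference of -4.16 (SE 0.09). AKR1C2 showed -4.75 (SE 0.13), but these paralogs are nearly identical and the AKR1C2 difference was -0.36 and not called without shared probe sets. The quinone reductase NQO1 fell by 2.33 (SE 0.08), and xanthine dehydrogenase XDH rose by 6.43 (SE 0.30). The list was lower as a group (camera adjusted p = 0.0069; adjusted p = 0.094 with an estimated correlation), and the call ended without shared probe sets (adjusted p = 0.15) or with only genes above the median level (adjusted p = 0.084). Of 27 genes of glutathione and antioxidant defence, 9 rose and 7 fell (10 and 8 adjusted over the list alone). GPX1 and the glutathione transferase GSTP1 led those that rose, GSTP1 with 13986 ± 519 against 104.1 ± 9.16 and a log2 difference of 6.86 (SE 0.09). The intestinal peroxidase GPX2 fell by 2.18 (SE 0.24). This list was not shifted (camera adjusted p = 0.95). Its mean was 0.43 while its median was -0.05 and the sign of the test was negative.

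Of 25 genes of the oestrogen receptor and its response, 21 fell and 1 rose (21 and 1 adjusted over the list alone). TFF1, a secreted peptide induced by oestrogen, had 50.7 ± 27.3 in MCF-7/ADR and 29116 ± 124 in MCF-7. The carbonic anhydrase CA12 fell by 6.49 (SE 0.36) and the progesterone receptor gene PGR fell by 3.08 (SE 0.17). MYBL1 was the member that rose, by 0.77 (SE 0.16), a call lost with arrays centred on their medians. The list was lower as a group (camera adjusted p = 1.1e-11; adjusted p = 0.042 with an estimated correlation). Of 24 luminal identity genes, 18 fell and 1 rose (18 and 1 adjusted over the list alone). Besides KRT19 and AGR2, AGR3 fell by 6.87 (SE 0.31). The luminal transcription factors GATA3 and FOXA1 had log2 differences of -3.43 (SE 0.07) and -4.62 (SE 0.18), and GATA3 kept a signal of 2614 ± 89.8 in MCF-7/ADR. TFAP2A rose by 1.44 (SE 0.10). Camera gave an adjusted p of 7.7e-11 for this list, with adjusted p = 0.062 with an estimated correlation.

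Basal and Mullerian marker lists were split. Of 11 measured basal mammary genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.33). The growth factor receptor EGFR rose by 4.22 (SE 0.12), from 132.0 ± 5.86 to 2768 ± 197, and the small heat shock gene CRYAB rose by 4.12 (SE 0.21). ITGB4 fell by 3.34 (SE 0.35) on its brightest probe set, with 0.20 when shared probe sets were left out. Of 19 Mullerian and ovarian genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.80). The Wilms tumour gene WT1, a marker of serous ovarian and mesothelial cells, rose by 5.44 (SE 0.29) and mesothelin, MSLN, by 4.34 (SE 0.29), beside PAX8. MECOM fell by 4.01 (SE 0.33).

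Of 25 genes of epithelial adhesion and splicing, 21 fell and none rose (21 and 0 adjusted over the list alone). CDH1 had a signal of 6.67 ± 5.31 in MCF-7/ADR and 24552 ± 524 in MCF-7. The vesicle transport gene RAB25 fell by 7.55 (SE 0.18) and the tight junction gene CLDN7 fell by 6.76 (SE 0.34). EPCAM, an epithelial surface protein, fell by 2.74 (SE 0.08) and kept 3203 ± 143 in MCF-7/ADR. The list was lower (camera adjusted p = 1.9e-12; adjusted p = 0.075 with an estimated correlation). Of 26 mesenchymal genes, 21 rose and 1 fell (21 and 1 adjusted over the list alone). CALD1, the matrix protein SPARC (8.0, SE 0.16) and the receptor kinase AXL (7.57, SE 0.26) led the list. The intermediate filament gene VIM had 21914 ± 1274 in MCF-7/ADR and 459.4 ± 2.35 in MCF-7, and ZEB1, a repressor of CDH1, rose by 5.48 (SE 0.28). CAV2 fell by 0.47 (SE 0.07), a call lost when the probe sets of a gene were averaged. Camera gave an adjusted p of 7.7e-11 for the mesenchymal list, with adjusted p = 0.094 with an estimated correlation.

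Of 34 integrin and extracellular matrix genes, 26 rose and 6 fell (26 and 6 adjusted over the list alone). MMP1 reached 28369 ± 1573 in MCF-7/ADR, from 28.1 ± 0.801 in MCF-7. The basement membrane genes NID2 and LAMA1 rose by 7.95 (SE 0.17) and 6.97 (SE 0.21), and the protease inhibitor TIMP3 fell by 3.28 (SE 0.30). The list was higher (camera adjusted p = 3.1e-07; adjusted p = 0.075 with an estimated correlation). Of 24 TGF-beta signalling genes, 9 rose and 8 fell (9 and 8 adjusted over the list alone; camera adjusted p = 0.90). The ligand BMP7 fell by 5.90 (SE 0.45) and ID2, a BMP target, fell by 4.72 (SE 0.15), while the co-receptor TGFBR3 rose by 4.58 (SE 0.19). Of 20 stem cell associated genes, 7 rose and 6 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.70). The hyaluronan receptor CD44 rose by 3.11 (SE 0.08) and ITGA6 by 3.34 (SE 0.12), and SOX2 fell by 4.88 (SE 0.20) on its brightest probe set, while of its 4 probe sets 2 were lower and 1 was higher. HMGA2 rose by 5.68 (SE 0.20) on 1 of its 9 probe sets, a call lost without shared probe sets.

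**Figure D2:**
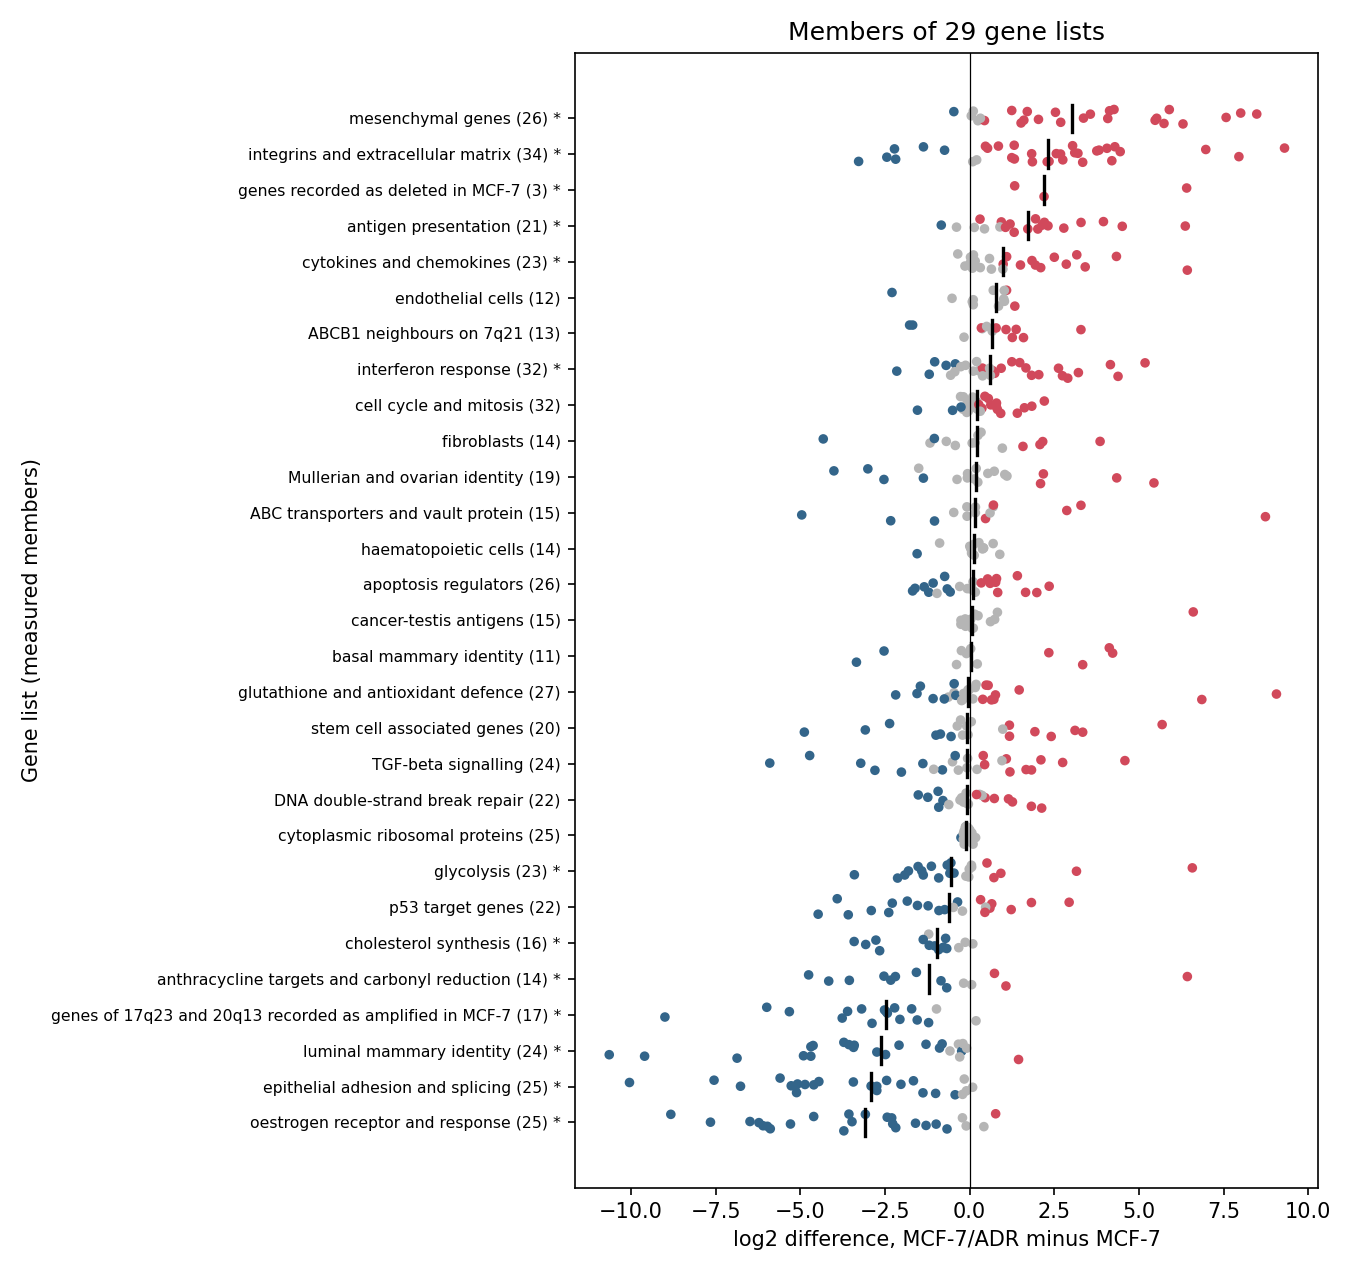
Log2 difference, MCF-7/ADR minus MCF-7, of each measured member of the 29 lists, with 1 point per gene and the number of measured members in brackets. Red points rose, blue points fell, grey points did not pass the test, the black bar is the list's median and a star marks the 13 lists called by camera; the medians of 9 lists change sign between scalings (ABC transporters, glutathione, basal, Mullerian, haematopoietic, fibroblast, apoptosis, cancer-testis and ribosomal protein genes).

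Markers of other cell types were mostly dim in both lines. Of 14 haematopoietic genes, none rose and 1 fell, CORO1A, with a log2 difference of -1.55 (SE 0.23), and 10 had a mean signal under 100 in both lines (0 and 1 adjusted over the list alone; camera adjusted p = 0.95). Of 12 endothelial genes, 2 rose and 1 fell, and 9 were under 100 in both lines (2 and 1 adjusted over the list alone; camera adjusted p = 0.62). EMCN fell by 2.29 (SE 0.42), and the calls of PECAM1 and ROBO4 were lost under at least 1 other setting. Of 14 fibroblast genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.65). The collagen gene COL5A1 fell by 4.32 (SE 0.41) and the transcription factor TCF21 rose by 2.16 (SE 0.46). Among 15 cancer-testis antigens 1 rose, PRAME, with 2619 ± 418 against 10.2 ± 5.09 and a log2 difference of 6.60 (SE 0.23), and the other 14 were under 100 in both lines (1 and 0 adjusted over the list alone; camera adjusted p = 0.64).

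Genes in regions recorded as lost or gained in MCF-7 formed 2 lists fixed from general knowledge. All 3 measured genes of the deleted list rose (3 and 0 adjusted over the list alone). The cell cycle inhibitor CDKN2A had 8639 ± 716 in MCF-7/ADR and 86.4 ± 23.7 in MCF-7, a log2 difference of 6.41 (SE 0.16). Its neighbours MTAP, a methionine salvage enzyme, and CDKN2B rose by 2.20 (SE 0.22) and 1.33 (SE 0.18). This list was higher (camera adjusted p = 0.0069; adjusted p = 0.14 with an estimated correlation). Of 17 genes of the 17q23 and 20q13 amplicons, 15 fell and none rose (16 and 0 adjusted over the list alone). SULF2, a heparan sulfatase, had 33.2 ± 23.5 in MCF-7/ADR and 24012 ± 1090 in MCF-7, and BCAS3 and TBX2 had log2 differences of -5.99 (SE 0.11) and -5.32 (SE 0.43). Camera gave an adjusted p of 2.5e-11, with adjusted p = 0.042 with an estimated correlation.

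Lists of cell cycle and DNA damage genes held members that rose and members that fell, and none of them was called as a group. Of 32 cell cycle genes, 14 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.062). The spindle checkpoint kinase BUB1 rose by 2.21 (SE 0.13), the mitotic motor CENPE by 1.84 (SE 0.37) and the G1/S cyclin CCNE1 by 1.62 (SE 0.11). MCM7 of the replicative helicase fell by 1.54 (SE 0.08). Of 22 p53 target genes, 7 rose and 12 fell (7 and 12 adjusted over the list alone; camera adjusted p = 0.052). TP53INP1 fell by 3.91 (SE 0.20), the p53 inhibitor MDM2 fell by 2.28 (SE 0.08) and the cell cycle inhibitor CDKN1A fell by 1.84 (SE 0.18), while TP53I3 rose by 2.94 (SE 0.09). GDF15 fell by 4.47 (SE 0.23) on its brightest probe set, with 0.34 when shared probe sets were left out. Of 26 apoptosis regulators, 11 rose and 8 fell (11 and 8 adjusted over the list alone; camera adjusted p = 0.95). The BCL2 relative BCL2A1 rose by 2.35 (SE 0.34) and the apoptosome gene APAF1 by 1.98 (SE 0.17), while BCL2L11, which promotes apoptosis, fell by 1.68 (SE 0.12), a call lost when the probe sets of a gene were averaged (-0.28). Of 22 genes of DNA double-strand break repair, 7 rose and 5 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.95). ATM, a kinase activated by breaks, rose by 1.82 (SE 0.26) and RAD51C fell by 1.52 (SE 0.08). The mean of that list was 0.06, its median -0.09 and the sign of its test negative.

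Of 32 interferon response genes, 16 rose and 5 fell (16 and 5 adjusted over the list alone). The antiviral genes MX2 and BST2 rose by 5.18 (SE 0.28) and 4.16 (SE 0.16), and CMPK2 fell by 2.15 (SE 0.39). IFI44 rose by 4.38 (SE 0.28) on 1 of its 2 probe sets, and the other gave -0.03. The list was higher (camera adjusted p = 0.012; adjusted p = 0.094 with an estimated correlation). Of 21 antigen presentation genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone). The immunoproteasome gene PSMB8 had 1736 ± 233 in MCF-7/ADR and 4.11 ± 0.157 in MCF-7, PSMB9 rose by 4.51 (SE 0.30) and the peptide transporter gene TAP2 by 3.95 (SE 0.16). B2M, the light chain of class I molecules, fell by 0.84 (SE 0.09). Probe sets of HLA genes can share targets, so single HLA values are uncertain. Camera gave an adjusted p of 2.4e-06, with adjusted p = 0.075 with an estimated correlation. Of 23 cytokines and chemokines, 12 rose and none fell (12 and 0 adjusted over the list alone), and 11 had a mean signal under 100 in both lines. IL18 rose by 6.43 (SE 0.10) and the chemokine CCL20 by 4.33 (SE 0.29). The list was higher (camera adjusted p = 0.0016; adjusted p = 0.094 with an estimated correlation), and the call ended when only genes above the median level were tested (adjusted p = 0.068).

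Of 16 cholesterol synthesis genes, 12 fell and none rose (14 and 0 adjusted over the list alone). INSIG1, a sterol sensor partner, fell by 3.41 (SE 0.11), from 4637 ± 236 to 422.7 ± 53.6, and the reductase DHCR7 fell by 2.77 (SE 0.14). Camera gave an adjusted p of 2.6e-07, with adjusted p = 0.042 with an estimated correlation. Of 23 glycolysis genes, 13 fell and 5 rose (13 and 5 adjusted over the list alone). The pyruvate dehydrogenase kinase PDK3 fell by 3.40 (SE 0.19), while the lactate dehydrogenase subunit LDHB rose by 6.58 (SE 0.10) and the glucose transporter SLC2A3 by 3.15 (SE 0.33). GAPDH had 24978 ± 1875 and 25400 ± 788, a difference of -0.03 that became 0.12 and passed the test with quantile normalisation. The glycolysis list had a camera adjusted p of 0.049 (adjusted p = 0.60 with an estimated correlation) and was called in 8 of 18 other settings. Of 25 cytoplasmic ribosomal protein genes, 1 fell, RPL18, and none rose (0 and 0 adjusted over the list alone; camera adjusted p = 0.24). The RPL18 call was lost under several other settings, among them scaling by medians or 75th percentiles. The median of the ribosomal protein list was -0.10, and 0.02 with quantile normalisation.

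RNA quality measures differed little between the lines. The log2 ratio of 3' to 5' control probe sets differed by 0.06 for ACTB (exact permutation p = 0.4, two-sided) and by -0.02 for GAPDH (p = 0.6). Across 7 control measures, hybridisation and labelling spikes included, the adjusted p was 0.7 for each, and the smallest p that 3 against 3 arrays allow is 0.1.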

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

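The tests in this part were chosen after the results were seen, except the refit over other splits of the arrays. Probe sets outside the comparison of named genes also differed. Of 11721 probe sets with no gene symbol, 741 were higher and 479 lower in MCF-7/ADR by at least 2-fold, and of 1801 with several symbols, 184 were higher and 156 lower. The largest log2 difference was 8.96 among those without a symbol and 9.35 among those with several.

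The first pattern is the size of the difference, with 8529 genes called between the lines. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many, the real one, and the highest of the others gave 0. The others mix the lines, which puts the line difference into the spread within groups, so their 0 does not measure chance. Also, 10 splits are too few for a share under 0.05. RNA degradation would have shifted the control ratios of ACTB and GAPDH, and the largest of 7 control differences was 0.12. These controls cannot exclude array handling. The 2 ratios had SDs of 0.04 and 0.03 in MCF-7/ADR, although its replicate 1 had raised dim probe sets. Without that array 8333 genes were called. A scaling error would have moved the ribosomal protein genes, whose median was -0.10 with an SD over genes of 0.10, though centring arrays on their medians took it to -0.32. Drug selection, separate culture, separate descent and array handling that differed between the lines stay open and were not told apart by these arrays.

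A second pattern is that some epithelial genes kept part of their signal in MCF-7/ADR although 21 of 25 epithelial adhesion genes fell. The 6 looked at, EPCAM, KRT8, KRT18, ERBB3, MUC1 and MLPH, were picked by hand and had between 14.9% and 85.1% of their MCF-7 signal. Of them only EPCAM is in the epithelial adhesion list, and MUC1 was down to 547 ± 119 in MCF-7/ADR. MCF-7 cells mixed into the MCF-7/ADR cultures would have carried all abundant MCF-7 transcripts at about one share. The 10 most lowered named genes had a median of 0.108% of their MCF-7 signal and at most 0.174%, which argues against such a mixture as the source of the EPCAM signal. A biological explanation was not tested.

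The third pattern is the signal of genes recorded as deleted in MCF-7. CDKN2A, MTAP and CDKN2B had a median log2 difference of 2.20, the lowest being 1.33. The raised dim probe sets of MCF-7/ADR replicate 1 do not account for it, since the median was 2.12 without that array. In MCF-7 the signal was 114.5 ± 28.0 for MTAP and 189.8 ± 16.2 for CDKN2B. MTAP was higher in MCF-7/ADR on 4 of its 6 probe sets and CDKN2B on 1 of 2. Without detection calls, loss of these genes in this MCF-7 stock was not shown. A candidate explanation is that the MCF-7/ADR cells did not descend from cells with the recorded deletion, which the value of 2.20 allows and does not prove. A founder subclone that kept the region, a different record for this MCF-7 stock, or cells of another origin under the MCF-7/ADR name, as has been reported for some stocks of that name, may each give the same values and were not told apart. Of 17 genes of regions recorded as amplified in MCF-7, 15 fell and none rose, which bears on descent too but was not weighed here.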

How the results depend on the processing

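Of 123 called named genes, 76 had a value under all 18 alternatives, and 66 of these kept direction and call. The others had no value without shared probe sets (31) or above the median level (20), some under both. Named genes that reversed did so with another choice of probe set, and none of these values passed the test: without probe sets shared between transcripts ITGB4 became 0.20, GDF15 0.34, IFI44 -0.026 and SC5D 0.094, and with probe sets averaged RPL18 became 0.022. Leaving out each array in turn gave 7428 to 8339 called genes. With arrays centred on their medians, 2653 genes were higher and 39.0% of calls were higher, against 50.5%, and the median of all genes moved from 0.09 to -0.13, so the balance of higher and lower genes depends on scaling. Testing only genes above the median level left 1443 higher and 1669 lower by at least 2-fold, against 2547 and 2280 among all genes. Fewer genes were tested, but that alone does not account for the larger loss among higher genes. Testing all probe sets called 16473, of which 8751 were higher and 7722 lower, and 5598 and 4455 by at least 2-fold, as more items were tested. Of the lists, 3 were called with an estimated correlation, 22 with fry for 1 direction and 28 with fry for any change; these test other questions or allow for correlation. With the replicate number as a block (replicate block), 8177 genes were called. Deviations of same-numbered arrays correlated at -0.04, 0.05 and -0.13, so no pairing by number was seen. Whether the numbers mark shared culture days is not stated in the sources used here. The calls of 10 lists held under all 18 alternatives of fit, scaling and arrays, and glycolysis in 8 of them. The lists of ABCB1 neighbours, p53 targets and cell cycle genes, which lay just above the threshold, passed it under some of these alternatives, and basal genes did when only genes above the median level were tested. Signal over background limits dim genes, and it was not measured here. The share of values below the offset was 16.96% on MCF-7/ADR replicate 1 and 26.0% to 27.1% on the other arrays. It is near 25% by the definition of the offset and does not measure background.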

Other observations

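Gene families sharing a symbol stem, genes on in 1 line only and neighbouring genes were examined after the gene table had been seen. Of 28 measured genes of the homeobox A to D clusters, which set position along the body axis, 19 rose and 2 fell in MCF-7/ADR (camera adjusted p = 0.0031 over 26 families; adjusted p = 0.58 with an estimated correlation). HOXD4 rose by 3.58 (SE 0.34) and HOXB2 by 3.52 (SE 0.33). All 7 metallothioneins, small metal-binding proteins, rose (adjusted p = 1.5e-04; adjusted p = 0.58 with an estimated correlation), MT1E by 3.63 (SE 0.09) and MT1X by 1.42 (SE 0.08). Their probe sets share targets, so the members are not independent. Of 12 BEX and TCEAL genes, 7 rose and 1 fell (adjusted p = 0.011; adjusted p = 0.58 with an estimated correlation), with BEX1 at 14649 ± 783 in MCF-7/ADR and 61.4 ± 1.22 in MCF-7. Of 57 histone genes, 22 fell and none rose (adjusted p = 0.0031; adjusted p = 0.69 with an estimated correlation), with log2 differences of -3.83 (SE 0.27) for H2BC21 and -2.20 (SE 0.10) for H2BC5. Both of these values came from probe sets of the shared kind, so histone members may not be independent either. The medians of these 4 families kept their sign under every scaling tried.

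Some genes were bright in 1 line and dim in the other. With at least 1000 on all 3 arrays of a line and under 100 on all 3 of the other, 144 genes were on in MCF-7/ADR only and 94 in MCF-7 only. The neurotrophin gene BDNF had 3502 ± 182 in MCF-7/ADR and 22 ± 15.8 in MCF-7, and the growth factor gene FGF2 had 2678 ± 215 and 15.2 ± 4.19. In the other direction, PDCD10, which is altered in familial cerebral cavernous malformations, had 22.9 ± 32.0 in MCF-7/ADR and 8205 ± 1673 in MCF-7, and the inflammasome adaptor gene PYCARD had 8.39 ± 4.35 and 2682 ± 263. UBB, which encodes a polyubiquitin, had 16.96 ± 16.3 and 31232 ± 1219 on its 1 probe set, and the probe set of its pseudogene UBBP1, whose sequence is close to that of UBB, fell by 4.53 (SE 0.32), from a signal of 1471 ± 323.

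A hypothesis was that neighbouring genes differ together. The predictions for these tests were written before their results were seen. In 9560 genes above the median level, placed in reference order, the largest mean over 21 neighbouring genes was 2.21. Over 1000 shuffled orders the 95th percentile of the largest mean was 1.67 and 0 orders gave as large a value, which argues against a chance order. Beyond that value lay 100 of 9120 windows, which formed 8 separate regions once blocks sharing genes were joined, 4 higher and 4 lower. From LRRC8C to CNN3, 18 of 21 genes were higher, and from YAP1 to DDX10, which holds BIRC2, MMP1 and CASP4, 20 of 21 were. YAP1 rose by 2.00 (SE 0.07). From ZNRF1 to SDR42E1, 20 of 21 were lower, with a mean of -1.96. Copy number differences between the lines may give such blocks, as may shared chromatin or paralogs, and none of these was measured. Around ABCB1, the mean of 20 neighbours without ABCB1 and ABCB4 was 0.52, at the 81.5th percentile of all windows, with 12 higher and 6 lower. Much of that mean came from 1 gene, SEMA3D, with a log2 difference of 7.51 (SE 0.14). A raised region there was neither shown nor excluded.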
